A study of Homo sapiens with 14 samples.

How the data were processed

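RNA sequencing of KYSE510 cells 48 h after siRNA transfection gave 12 libraries in 2 series, each with 2 siRNAs against 1 target and its own siNC, 2 libraries per group. The authors gave FPKM (reads or fragments counted, scaled by gene length and by library depth) to 2 decimals in 1 deposited table per series, with 1 column per library. The submitters' processing notes name Bowtie, STAR, Bowtie2, Trim Galore, Picard and SEACR and the builds hg19 and hg38, without saying which made these tables. The counting program, the gene lengths and the strand setting are not stated. In the LAT1 series the titles give both siNC libraries the same replicate number and the descriptions number them apart; the descriptions were followed, and the values of these libraries differ. The 2 EZH2 CUT&Tag samples, from KYSE510 and FADU cells, were not analysed here.

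Columns summed to between 245634 and 275399 FPKM over 63677 genes. Depth was recovered from short RNA genes, whose low FPKM values rise in steps of 1 read. The depth chosen made 87.9% to 92.2% of these values whole numbers of reads within 0.12 reads. A depth fixed beforehand would give 24% by chance. Since the depth was the best of many searched, its own chance value is higher and was not found. The depth is an estimate, and whether reads or fragments were counted is unknown. Intervals from the fit cover the spread between libraries only.

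Each table was fitted alone. The plan was a count-based test if the tables held counts and otherwise limma-trend on log2 values, and since they held FPKM the latter was used. Genes with a mean of at least 1 FPKM over the 6 libraries of a table were kept, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with 1 group per siRNA and siNC. Contrasts were the mean of both siRNAs minus siNC, each siRNA minus siNC and the second siRNA minus the first. Calls were made at an adjusted p (Benjamini-Hochberg) under 0.05, two-sided, and intervals are at 95%. An exact permutation test of 4 libraries against 2 cannot give a p under 0.0667, so the calls rest on the model's spread pooled across genes. Nothing states that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Shared calls were compared with the number expected if calls in both series were independent. Because both siRNAs of a series share siNC libraries, data without change were simulated 100 times to see what their chance spread alone gives. siRNA values were drawn around the siNC mean with noise independent for each gene. The simulation therefore could not hold a change made by siNC itself, or a part that libraries share across genes.

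The groups, tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. The 28 lists were PRC2 subunits, PRC1 subunits, Polycomb-target developmental regulators, genes reported as EZH2-repressed in carcinoma cells, the amino acid response with ATF4 targets, cytosolic aminoacyl-tRNA synthetases, amino acid transporters, methionine, folate and polyamine metabolism, histone and DNA methyltransferases and demethylases, sterol synthesis, S phase, G2 and mitosis, basal squamous identity, terminal squamous differentiation, mesenchymal transition, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory mediators, p53-responsive genes, the unfolded protein response, hypoxia and glycolysis, autophagy and lysosome, mitochondrial transcripts, ribosomal proteins, replication-dependent histones, and fibroblast, immune and endothelial markers. Of 962 symbols listed, 961 were found and 672 were tested in the EZH2 series and 724 in the LAT1 series. The first 25 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation, with fry and with each siRNA alone. Named genes were EZH2, SLC7A5, SLC3A2, the 10 highest and 10 lowest log2 fold changes per main comparison among genes called with the mean and with both siRNAs and with an average log2 value of at least 2, up to 4 members per list, the 10 largest shared changes and the 4 largest differences per direction between siRNAs. Some genes that met this rule are not reported here. SUZ12 and PITX1 were named after their values were seen.

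Alternatives were quantile normalization, a pseudocount of 0.1, no filter, a filter at 5 FPKM, both siRNAs pooled as 1 group, a minimum absolute log2 fold change of 1, replicate number as a block and each library left out in turn. The procedure was tested on simulated data with 50 changed genes per step and noise independent for each gene. At a log2 change of 0.5 it called 92% of them at the EZH2 series' spread and 86% at the LAT1 series' spread. It called 16 and 14 unchanged genes. The real fits called 30.0% and 34.5% of genes, a far larger share than was changed in simulation. The simulated rates therefore need not hold in the real data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.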

Results

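RNA was sequenced from KYSE510, an esophageal squamous cell carcinoma line, 48 h after transfection with small interfering RNA (siRNA). The 12 libraries formed 2 series of 6. In the EZH2 series, siEZH2-1, siEZH2-2 and the negative control siNC had 2 libraries each. In the LAT1 series, siLAT1-2, siLAT1-3 and a separate siNC had 2 libraries each. EZH2 is the histone methyltransferase of Polycomb repressive complex 2 (PRC2). LAT1, the product of SLC7A5, carries large neutral amino acids such as leucine and methionine into cells, and its heavy chain is the product of SLC3A2. Each library listed 63677 genes in FPKM, and between 11465 and 11794 of them stood at 1 FPKM or more. Depth recovered from the steps between low values ran from 21060000 to 27180000 counted reads or fragments in the EZH2 series and from 12760000 to 16700000 in the LAT1 series. Libraries of the same group correlated at r = 0.993 to 0.995 across genes, and the SD of their log2 difference was 0.161 to 0.194. Markers of other cell types were close to absent. The mean of COL1A1, a fibroblast collagen, was 1.23 FPKM in the EZH2 series and 2.00 FPKM in the LAT1 series, the highest mean of any fibroblast, immune or endothelial marker. Of the 11 fibroblast, 15 immune and 8 endothelial markers, 1, 1 and 0 reached the filter in the EZH2 series and 1, 0 and 1 in the LAT1 series, and none of those was called.

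The comparison of siEZH2 with siNC asks what loss of EZH2 transcript does to the transcriptome. EZH2 (ENSG00000106462) measured 6.94 ± 0.431 FPKM (SD, n = 2) with siEZH2-1 and 6.22 ± 0.255 FPKM with siEZH2-2, against 17.1 ± 0.0354 FPKM with siNC. These are 40.6% and 36.4% of the siNC level, a log2 fold change of -1.26 ± 0.0577 (SE; limma adjusted p = 1.24e-04) for the mean of both siRNAs. The difference in EZH2 between the siRNAs was -0.14 log2 (95% interval -0.30 to 0.02, adjusted p = 0.223). The transporter genes fell unequally. SLC7A5 (ENSG00000103257) stood at 188 ± 6.25 FPKM with siEZH2-1, 593 ± 3.73 FPKM with siEZH2-2 and 755 ± 31.3 FPKM with siNC, so that 24.9% and 78.6% of the siNC level remained. SLC3A2 (ENSG00000168003) stood at 69.7 ± 2.76, 176 ± 5.52 and 199 ± 13.9 FPKM, or 35.1% and 88.7% of siNC. SLC7A5 was called with both siRNAs (log2 -1.998 and -0.35, adjusted p = 2.5e-05 and 6.42e-03), whereas SLC3A2 was called with siEZH2-1 (log2 -1.50, adjusted p = 1.09e-04) and did not pass with siEZH2-2 (log2 -0.17, adjusted p = 0.107). The mean change of SLC7A5 was -1.17 and that of SLC3A2 -0.83; with both siRNAs pooled as 1 group of 4 libraries, neither passed (adjusted p = 0.211 and 0.262).

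**Figure D1:**
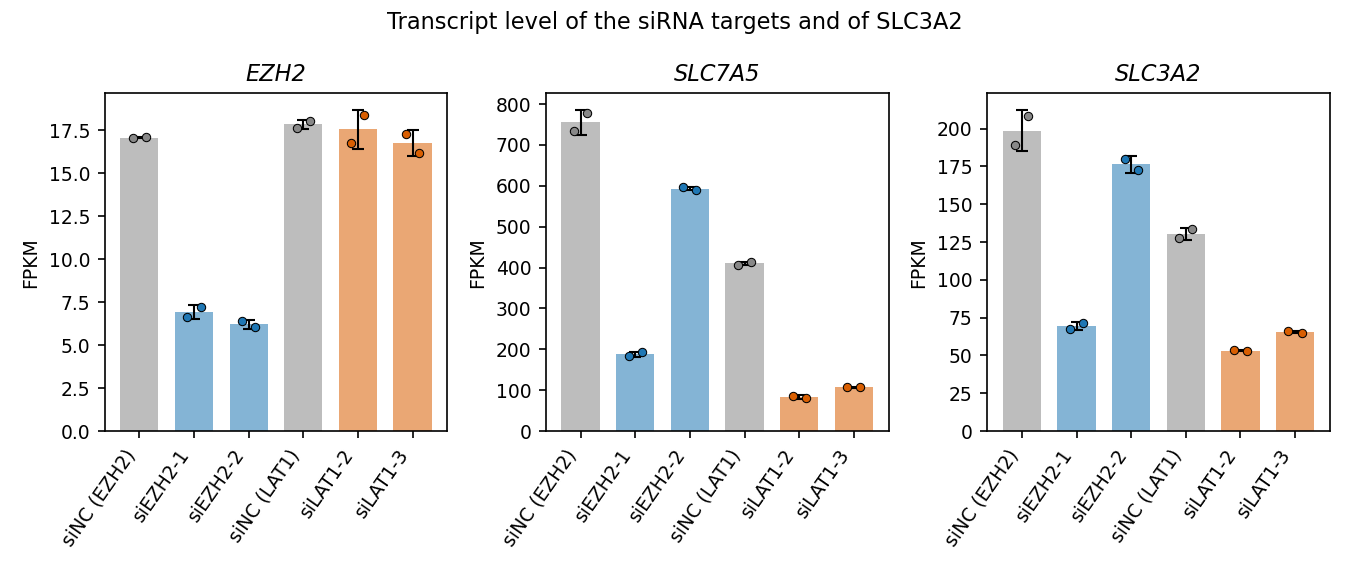
Transcript level in FPKM (y axis, from 0) of EZH2, SLC7A5 and SLC3A2 in the 6 groups; bars are means of 2 libraries, error bars 1 SD and points the libraries. EZH2 fell to 40.6% and 36.4% of siNC with siEZH2-1 and siEZH2-2 and measured 98.4% and 93.8% of siNC with siLAT1-2 and siLAT1-3, while SLC7A5 was at 24.9% of siNC with siEZH2-1 and 78.6% with siEZH2-2.

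The genes named first rose or fell with both EZH2 siRNAs. OGFR, the opioid growth factor receptor, rose from 4.83 ± 0.339 FPKM in siNC to 23.0 ± 2.38 and 22.3 ± 1.48 FPKM (log2 2.02 ± 0.0786, adjusted p = 8.7e-05). TPM4, a tropomyosin, rose from 23.7 ± 0.0212 to 98.6 ± 0.898 and 91.3 ± 0.587 FPKM (log2 1.96). Other genes with large rises called with both siRNAs were GANAB (log2 1.83), a subunit of the glycoprotein-trimming glucosidase of the endoplasmic reticulum, NOLC1 (1.72), a nucleolar phosphoprotein, ZW10 (1.63), a kinetochore protein, ZNF138 (1.52), RGS19 (1.52), STX12 (1.45) and WBP4 (1.45). CCND1, which encodes cyclin D1, fell the furthest, from 110 ± 4.97 FPKM to 13.9 ± 0.834 and 40.9 ± 3.29 FPKM (log2 -2.15 ± 0.0657, adjusted p = 4.41e-05). TGFBR2, a receptor for TGF-beta, fell by 1.48 on the log2 scale, SEC23A, a coat protein of secretory vesicles, by 1.39, and AMMECR1 by 1.39. UGCG, the glucosylceramide synthase, fell by 1.30, ELK3 by 1.26, THBS1 (thrombospondin) by 1.22 and TNRC6A, a partner of Argonaute in microRNA silencing, by 1.17. These are means of both siRNAs. In siEZH2-2 minus siEZH2-1, TGFBR2 differed by log2 -2.03, SEC23A by 1.22 and THBS1 by -1.04. TGFBR2, SEC23A and THBS1 lost their calls with both siRNAs pooled as 1 group (limma adjusted p = 0.199, 0.0802 and 0.0745). Of 11585 genes tested, 3481 were called, 1972 higher and 1509 lower, and 67 of the higher and 22 of the lower moved by at least 1 on the log2 scale. With siEZH2-1 alone 76 genes were higher and 83 lower by that much, and with siEZH2-2 alone 71 and 73. Quantile normalization gave 1747 higher and 1728 lower. Both siRNAs called 1504 genes in the same direction, 1035 higher and 469 lower, and 66 in opposite directions. The count of 3481 became 1360 without siNC replicate 1, 2050 without siNC replicate 2 and 2239 without siEZH2-1 replicate 2, and the count of 1504 became 619 without siNC replicate 1, 742 without siEZH2-1 replicate 2, 927 without siNC replicate 2, 941 without siEZH2-2 replicate 1 and 976 without siEZH2-1 replicate 1. Both siRNAs were set against the same pair of siNC libraries, which by itself makes their changes alike. In 100 simulated data sets with no true change, the changes correlated at r = 0.5 on average across genes (highest 0.539) and 0.01 genes on average were called with both, against an observed r of 0.619 and 1504 genes; independent calls would give 257 higher and 143 lower. The simulation holds only chance spread that is independent for each gene, so a change made by siNC itself could still lie behind calls with both siRNAs. Genes are not independent replicates.

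The Polycomb lists did not rise together after EZH2 knockdown. Of 13 PRC2 subunits tested, 6 were higher and 3 lower (7 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.547). EZH2, the siRNA target, is 1 of the 3 lower members. Its knockdown therefore weighs on this list, which was not tested without it. JARID2 (log2 0.45) and the histone chaperone RBBP4 (0.38) rose while EZH2 fell. SUZ12, a core subunit, stood at 5.72 ± 0.509 FPKM with siEZH2-1, 14.8 ± 1.58 with siEZH2-2 and 13.3 ± 1.29 with siNC, so it fell with siEZH2-1 (log2 -1.09, adjusted p = 9.87e-04); its mean change of -0.48 lost the call without siNC replicate 1 (adjusted p = 0.0764). Of 20 PRC1 subunits, 4 were higher and 3 lower (4 and 6 adjusted over the list alone; list adjusted p = 0.883), with KDM2B (log2 0.84) and CBX2 (0.55) up and BMI1 (-0.53, not called with siEZH2-2 alone) down. Among 91 developmental regulators known as Polycomb targets, 18 were tested; 1 was higher, 6 lower and 11 did not pass (1 and 7 adjusted over the list alone). SOX7 fell by 0.74 and GATA3 by 0.47 on the log2 scale, and the member that was higher was PITX1 (log2 0.44, with adjusted p = 0.0587 without siEZH2-1 replicate 2 and 0.141 without siNC replicate 1). As a list they were lower (median log2 -0.125, adjusted p = 0.0157), with adjusted p = 0.267 with an estimated correlation; the call was lost without siNC replicate 2 (adjusted p = 0.0859) and with siEZH2-2 alone (0.122). Of the genes reported as EZH2-repressed in carcinoma cells, 1 of 17 was higher and 5 lower (1 and 8 adjusted over the list alone; adjusted p = 0.0157, and adjusted p = 0.225 with an estimated correlation). Among them DKK1, a Wnt antagonist, fell by 0.82 and CDKN1A, the cell cycle inhibitor p21, by 0.89. Of 41 histone and DNA methyltransferases and demethylases, 5 were higher and 4 lower (5 and 3 adjusted over the list alone; list adjusted p = 0.769, the median -0.02 and the mean 0.02 differing in sign), with KDM2A (log2 0.69) and DOT1L (0.70) up.

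More genes of DNA replication were higher than lower with siEZH2, and more mitotic genes were lower than higher. Of 49 S phase genes, 27 were higher, 1 lower and 21 did not pass (32 and 1 adjusted over the list alone), for example UNG (log2 0.54), GINS2 (0.48) and ORC6 (0.44). The list was higher (adjusted p = 3.61e-07, and adjusted p = 0.225 with an estimated correlation). Of 48 genes of G2 and mitosis, 4 were higher, 12 lower and 32 did not pass (the same numbers adjusted over the list alone; adjusted p = 5.93e-03, and adjusted p = 0.315 with an estimated correlation), with AURKA (log2 -0.48) and the cytokinesis gene ANLN (-0.86) down and MYBL2 (0.46) up. Among replication-dependent histones, 5 of 12 were higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 2.63e-03, and adjusted p = 0.267 with an estimated correlation), among them HIST1H2BD (log2 1.10) and HIST1H2AC (0.59 on average, but 0.18 and not called with siEZH2-2); with siEZH2-2 alone this list was not called (adjusted p = 0.345). Of 26 p53-responsive genes, 3 were higher and 10 lower (3 and 14 adjusted over the list alone; adjusted p = 0.0157, and adjusted p = 0.225 with an estimated correlation). FAS (log2 -0.68) and GADD45A (-0.63) fell while XPC (0.58) rose, and with siEZH2-1 alone the list was not called (adjusted p = 0.229).

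In the squamous differentiation, mesenchymal, inflammatory and interferon lists, fewer members were higher than lower with siEZH2. Of 31 basal squamous genes, 6 were higher and 14 lower (6 and 17 adjusted over the list alone; adjusted p = 0.0139, and adjusted p = 0.225 with an estimated correlation). TFAP2A fell (log2 -0.62), while the junction gene PERP (0.86), COL17A1 (0.57) and the keratin KRT15 (1.11) rose; with siEZH2-1 alone the adjusted p was 0.0605. Of 17 genes of terminal squamous differentiation, 1 was higher and 2 lower, as also when adjusted over the list alone, the lower being EMP1 (log2 -0.77) and KRT80 (-0.47). That count of lower members is near the share over all genes, 1509 of 11585. That list was lower (adjusted p = 0.046, and adjusted p = 0.315 with an estimated correlation), but not without siEZH2-1 replicate 1 (0.0753), siEZH2-2 replicate 2 (0.141) or siNC replicate 2 (0.161), nor with siEZH2-1 alone (0.365). Of 26 mesenchymal genes, 2 were higher and 9 lower (2 and 9 adjusted over the list alone; adjusted p = 0.0186, and adjusted p = 0.225 with an estimated correlation), with PLAU (log2 -0.55) and THBS1 down and CYR61 (0.50) up; with siEZH2-1 alone the adjusted p was 0.0804. Of 18 NF-kB and inflammatory mediators, 2 were higher and 7 lower (2 and 9 adjusted over the list alone; adjusted p = 2.2e-03, and adjusted p = 0.225 with an estimated correlation). The acute-phase gene SAA1 fell by 1.13, TNFAIP2 by 0.89 and the apoptosis inhibitor BIRC3 by 0.86 on the log2 scale. Of 24 interferon-stimulated genes, 2 were higher and 7 lower (2 and 7 adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.315 with an estimated correlation), IFIT3 (log2 -0.47) and DDX58 (-0.48) among the lower; with siEZH2-2 alone the adjusted p was 0.115. Of 18 antigen presentation genes, 3 were higher, PSMB8 (log2 0.38) among them, and 3 lower (3 and 3 adjusted over the list alone; list adjusted p = 0.633).

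Among metabolic genes, the amino acid transporters included SLC7A5 and SLC3A2. Of 18, 2 were higher and 6 lower (3 and 8 adjusted over the list alone; adjusted p = 9.81e-03, and adjusted p = 0.225 with an estimated correlation). The cystine transporter SLC7A11 averaged log2 -0.71, with -0.16 (not called) for siEZH2-1 and -1.26 for siEZH2-2, and lost its call without the filter on low values (adjusted p = 0.0541) and with both siRNAs pooled (0.266). SLC43A2 averaged 0.46, with 0.15 (not called) and 0.77, and lost its call when pooled (adjusted p = 0.223). Of 38 genes of the amino acid response, 6 were higher, LONP1 (log2 0.83) among them, and 13 lower (9 and 14 adjusted over the list alone; list adjusted p = 0.178, and 0.0239, lower, with siEZH2-2 alone). Cytosolic aminoacyl-tRNA synthetases were split, 2 of 20 higher and 2 lower (2 and 2 adjusted over the list alone; list adjusted p = 0.598), with KARS at log2 0.38 and TARS at -0.37. Of 28 genes of methionine, folate and polyamine metabolism, 3 were higher and 8 lower (3 and 8 adjusted over the list alone; list adjusted p = 0.214). MAT2B, the regulatory subunit of methionine adenosyltransferase, stood at 9.72 ± 0.594 FPKM with siEZH2-1, 33.7 ± 0.806 with siEZH2-2 and 29.1 ± 1.43 with siNC, and MTRR fell (log2 -0.73). Sterol synthesis had 8 of 29 higher and 7 lower (9 and 8 adjusted over the list alone; list adjusted p = 0.769), with FDPS at log2 0.40 and SCD at -0.58 on average (-1.10 with siEZH2-1, and -0.06 and not called with siEZH2-2). In the synthetase, methionine and sterol lists the median was above 0 while the test pointed down. Hypoxia and glycolysis had 5 of 32 higher and 9 lower (5 and 9 adjusted over the list alone; list adjusted p = 0.169), with PFKL at log2 0.72, SLC2A1 at -0.53 and LDHA at -0.35. The unfolded protein response had 2 of 23 higher and 4 lower, HERPUD1 (log2 -0.54) among them (2 and 4 adjusted over the list alone; list adjusted p = 0.0822, and 0.0355, lower, with siEZH2-2 alone). Autophagy and lysosome genes had 6 of 35 higher and 6 lower (6 and 6 adjusted over the list alone; list adjusted p = 0.507), with the kinase gene ULK1 (log2 0.73) among the higher. Of the mitochondrial transcripts, 5 of 15 were higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 3.51e-03, and adjusted p = 0.549 with an estimated correlation), MT-ND5 at log2 0.40 among them, but not with quantile normalization (0.0866), and MT-ND5 lost its call without siNC replicate 2 (adjusted p = 0.0525). Ribosomal protein genes had 3 of 74 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.825 with an estimated correlation); the list was not called without siEZH2-1 replicate 2 (0.147), siEZH2-2 replicate 1 (0.219) or siNC replicate 1 (0.697), nor with siEZH2-1 alone (0.109). Mitochondrial, ribosomal and histone genes share sequence with paralogs or pseudogenes, which leaves their values uncertain.

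The EZH2 siRNAs differed from each other at many genes other than EZH2. Genes far lower with siEZH2-2 than with siEZH2-1 were TGFBR2 (8.87 ± 0.29 against 39.2 ± 1.96 FPKM, n = 2), the leptin receptor overlapping transcript LEPROT (log2 difference -1.86), the mitochondrial ribosome gene MRPL24 (-1.82) and the vesicle cargo receptor TMED10 (-1.60). In the other direction stood the small GTPase gene RAB12 (15.1 ± 0.714 against 3.34 ± 0.127 FPKM), C12orf23 (log2 difference 1.74), LEO1, a subunit of the PAF transcription elongation complex (1.70), and MAT2B (1.70). SLC7A5 (1.65), SLC3A2 (1.33) and CCND1 (1.49) were likewise lower with siEZH2-1. In all, 1883 genes differed, 857 higher and 1026 lower with siEZH2-2. The count was 650 without siEZH2-1 replicate 2, 841 without siEZH2-2 replicate 2, 859 without siEZH2-1 replicate 1 and 1238 without siEZH2-2 replicate 1.

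The comparison of siLAT1 with siNC asks what loss of the transporter transcript does, and whether EZH2 changes with it. SLC7A5 fell from 410 ± 4.39 FPKM (SD, n = 2) in siNC to 83.3 ± 4.16 FPKM with siLAT1-2 and 107 ± 0.318 FPKM with siLAT1-3, that is to 20.3% and 26.0% (log2 -2.11 ± 0.0318, limma adjusted p = 5.79e-07). Its partner SLC3A2, which neither siRNA is named for, fell from 131 ± 3.93 to 53.2 ± 0.17 and 65.6 ± 0.849 FPKM, or to 40.8% and 50.3% (log2 -1.13 ± 0.0265, adjusted p = 3.76e-06). EZH2 was not detectably changed, at 17.6 ± 1.15 and 16.8 ± 0.764 FPKM against 17.9 ± 0.262 FPKM (log2 -0.06 ± 0.0465, 95% interval -0.17 to 0.06, adjusted p = 0.397). The genes that rose the most were again OGFR (log2 1.78), TPM4 (1.62), NOLC1 (1.57), RGS19 (1.54) and GANAB (1.53), followed by ZNF845 (1.48), ZW10 (1.46), ZNF138 (1.44) and the neutrophil chemokine CXCL1 (1.44). CXCL1 went from 23.5 ± 0.721 FPKM to 70.8 ± 2.66 and 60.1 ± 1.05 FPKM. After SLC7A5 and SLC3A2, the genes that fell the furthest with both siRNAs were ENTPD7 (log2 -1.03), TNRC6A (-1.03), CDKN1A (-1.02), REEP3 (-0.9995), the protease-activated receptor gene F2RL1 (-0.99), C12orf49 (-0.97), the caveolin gene CAV2 (-0.95) and LRRC8B (-0.93). Of 11678 genes tested, 4032 were called, 2249 higher and 1783 lower, 42 and 9 of them by at least 1 on the log2 scale. With siLAT1-2 alone 52 genes were higher and 47 lower by that much, and with siLAT1-3 alone 48 and 49. Quantile normalization gave 1983 higher and 2005 lower. The count was 2288 without siNC replicate 1 and 2308 without siNC replicate 2. Both siRNAs called 1928 genes in the same direction, 1308 higher and 620 lower, and 171 in opposite directions; the first count was 1096 without siNC replicate 1 and 1139 without siNC replicate 2. Simulation without true change gave r = 0.504 on average across genes (highest 0.568) and 0.02 genes called with both. The observed r was 0.57 and the observed count 1928 genes, where independent calls would give 388 higher and 221 lower. As in the EZH2 series, the simulation could not hold a change made by siNC itself.

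With siLAT1, more amino acid response genes were higher than lower. Of 39 tested, 20 were higher and 5 lower (21 and 5 adjusted over the list alone; adjusted p = 5.25e-03, and adjusted p = 0.236 with an estimated correlation). TRIB3, an ATF4 target, rose by a log2 of 0.90 and the alanine aminotransferase GPT2 by 0.70, while SLC7A5 and SLC3A2, which the list also holds, fell; with siLAT1-2 alone the list was not called (adjusted p = 0.142). Cytosolic aminoacyl-tRNA synthetases had 9 of 20 higher, KARS (log2 0.33) among them, and 1 lower, TARS (-0.14), with the same numbers adjusted over the list alone. Their call (adjusted p = 0.0407, and adjusted p = 0.418 with an estimated correlation) was lost with quantile normalization (0.0868), with either siRNA alone (0.0914 and 0.119), without siLAT1-3 replicate 2 (0.0675) and without siNC replicate 1 (0.101). Of 20 amino acid transporters, 3 were higher and 6 lower (3 and 6 adjusted over the list alone; list adjusted p = 0.0909), SLC7A1 (log2 0.37) and SLC1A5 (0.30) being among the higher. The lower include SLC7A5, the siRNA target, and SLC3A2. Methionine, folate and polyamine metabolism had 8 of 31 higher and 4 lower (9 and 4 adjusted over the list alone; list adjusted p = 0.0953, and 0.0286, higher, with siLAT1-2 alone), CTH (log2 0.44) being among the higher. The methionine salvage gene ADI1 was called in opposite directions, at 0.21 with siLAT1-2 and -0.86 with siLAT1-3. Of 32 sterol synthesis genes, 6 were higher and 13 lower (8 and 13 adjusted over the list alone), HMGCS1 (log2 -0.84) among the lower. The sterol call (adjusted p = 0.0407, and adjusted p = 0.477 with an estimated correlation) was lost with quantile normalization (0.0868), with siLAT1-2 alone (0.451) and without siLAT1-2 replicate 2 (0.0971), siLAT1-3 replicate 1 (0.0733) or siNC replicate 1 (0.0538). Of the hypoxia and glycolysis genes, 2 of 34 were higher and 18 lower (2 and 21 adjusted over the list alone; adjusted p = 1.21e-04, and adjusted p = 0.477 with an estimated correlation), with HIF1A at log2 -0.53, TPI1 at -0.63 and LDHA at -0.38. TPI1 differed between the siRNAs (siLAT1-3 minus siLAT1-2, log2 -0.94) and lost its call when pooled (adjusted p = 0.267). The unfolded protein response had 8 of 24 higher and 2 lower (9 and 2 adjusted over the list alone; list adjusted p = 0.0903), with CRELD2 at log2 0.38 and SEL1L at -0.27. Autophagy and lysosome genes had 4 of 34 higher and 6 lower (4 and 6 adjusted over the list alone; list adjusted p = 0.379), with BECN1 at log2 0.23. LAMP1 was at -0.63 with siLAT1-2 and 0.03, not called, with siLAT1-3.

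Among PRC2 subunits, EZH2 itself did not pass with siLAT1 while others were higher. Of 13, 8 were higher and 0 lower, as also when adjusted over the list alone (adjusted p = 5.25e-03, and adjusted p = 0.236 with an estimated correlation), including PHF19 (log2 0.31); neither siRNA alone gave the call (adjusted p = 0.0827 and 0.0768). RBBP4 (0.21 on average) was at -0.06, not called, with siLAT1-2 and at 0.47 with siLAT1-3, and lost its call when pooled (adjusted p = 0.516). Of 20 PRC1 subunits, 8 were higher and 1 lower (8 and 2 adjusted over the list alone; list adjusted p = 0.069), KDM2B (log2 0.71) and CBX6 (0.40) among the higher. Polycomb-target regulators had 6 of 29 higher and 1 lower (5 and 1 adjusted over the list alone; list adjusted p = 0.664), with HOXA9 (log2 0.78) and HOXC10 (0.56) higher and MSX2 (-0.39) lower. Genes reported as EZH2-repressed had 3 of 19 higher, IGFBP3 (log2 0.40) among them, and 3 lower (3 and 4 adjusted over the list alone; list adjusted p = 0.588). Of 41 histone and DNA methyltransferases and demethylases, 10 were higher and 8 lower (10 and 8 adjusted over the list alone; list adjusted p = 0.458), with KDM2A (log2 0.74) and DOT1L (0.59) up.

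With siLAT1 too, more S phase genes were higher than lower, and more mitotic genes were lower than higher. Of 49 S phase genes, 26 were higher and 3 lower (27 and 3 adjusted over the list alone; adjusted p = 1.21e-04, and adjusted p = 0.392 with an estimated correlation), with MCM3 (log2 0.39) and ORC1 (0.48) up and DSCC1 (-0.51) down. Of 48 mitotic genes, 5 were higher and 20 lower (5 and 20 adjusted over the list alone; adjusted p = 3.41e-04, and adjusted p = 0.236 with an estimated correlation), among them TOP2A (log2 -0.45), AURKA (-0.35) and CCNB1 (-0.28). Of 26 p53-responsive genes, 3 were higher and 7 lower (3 and 9 adjusted over the list alone), MDM2 (log2 -0.89) and CDKN1A among the lower. The p53 call (adjusted p = 0.0407, and adjusted p = 0.326 with an estimated correlation) was lost with quantile normalization (0.056), with siLAT1-2 alone (0.0914) and without siLAT1-2 replicate 2 (0.0611), siLAT1-3 replicate 1 (0.0571) or siNC replicate 1 (0.0586). Replication-dependent histones had 0 of 13 higher and 2 lower, HIST1H2BK (log2 -0.55) among them (0 and 1 adjusted over the list alone; list adjusted p = 0.057). That list was called lower with siLAT1-3 alone (adjusted p = 8.02e-03) and without siLAT1-2 replicate 1 (0.0147), siLAT1-3 replicate 2 (0.0186) or siNC replicate 2 (0.0413). Of the basal squamous genes, 5 of 34 were higher and 18 lower (6 and 19 adjusted over the list alone; adjusted p = 1.28e-03, and adjusted p = 0.236 with an estimated correlation). The laminin-binding integrins ITGA3 (log2 -0.50) and ITGB4 (-0.33) fell while PERP (0.87) and COL17A1 (0.44) rose, and with siLAT1-3 alone the list was not called (adjusted p = 0.0934). Of the terminal squamous differentiation genes, 1 of 23 was higher and 10 lower (1 and 11 adjusted over the list alone; adjusted p = 4.06e-04, and adjusted p = 0.326 with an estimated correlation), among them KRT80 (log2 -0.62), SERPINB1 (-0.22) and SLPI (-0.40 on average, but -0.12 and not called with siLAT1-3). Mesenchymal genes were mixed, 8 of 32 higher and 11 lower (8 and 12 adjusted over the list alone; list adjusted p = 0.26), with COL4A1 (log2 0.57) and CYR61 (0.61) higher. TGFBI was called in opposite directions, at -0.68 with siLAT1-2 and 0.21 with siLAT1-3. Of the inflammatory mediators, 16 of 27 were higher and 1 lower (16 and 2 adjusted over the list alone; adjusted p = 1.8e-03, and adjusted p = 0.236 with an estimated correlation), led by CXCL1, PTGS2 (log2 0.84), IL8 (0.61) and SOD2 (0.50), though not with siLAT1-3 alone (adjusted p = 0.0934). Interferon-stimulated genes had 2 of 29 higher and 7 lower (2 and 7 adjusted over the list alone; list adjusted p = 0.26), IFIT2 at log2 -0.77 and SAMD9 at -0.36. Antigen presentation had 4 of 18 higher, CALR (log2 0.18) among them, and 1 lower (3 and 0 adjusted over the list alone; list adjusted p = 0.329). Of the mitochondrial transcripts, 0 of 15 were higher and 5 lower (0 and 6 adjusted over the list alone; adjusted p = 4.3e-03, and adjusted p = 0.546 with an estimated correlation), but not with quantile normalization (0.122) or with siLAT1-3 alone (0.0934). MT-CYB (log2 -0.39, and -0.28 and not called with siLAT1-3 alone) lost its call without siLAT1-3 replicate 1 (adjusted p = 0.0857), siLAT1-3 replicate 2 (0.056), siNC replicate 1 (0.125) or siNC replicate 2 (0.18), and with quantile normalization (0.0545). Ribosomal protein genes had 2 of 73 higher and 18 lower, RPL35A (log2 -0.41) among them (2 and 17 adjusted over the list alone; adjusted p = 1.21e-04, and adjusted p = 0.418 with an estimated correlation), but the list was not called with quantile normalization (0.131) or with siLAT1-3 alone (0.127). Mitochondrial, ribosomal and histone values carry the same uncertainty from paralogs and pseudogenes as in the EZH2 series.

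**Figure D2:**
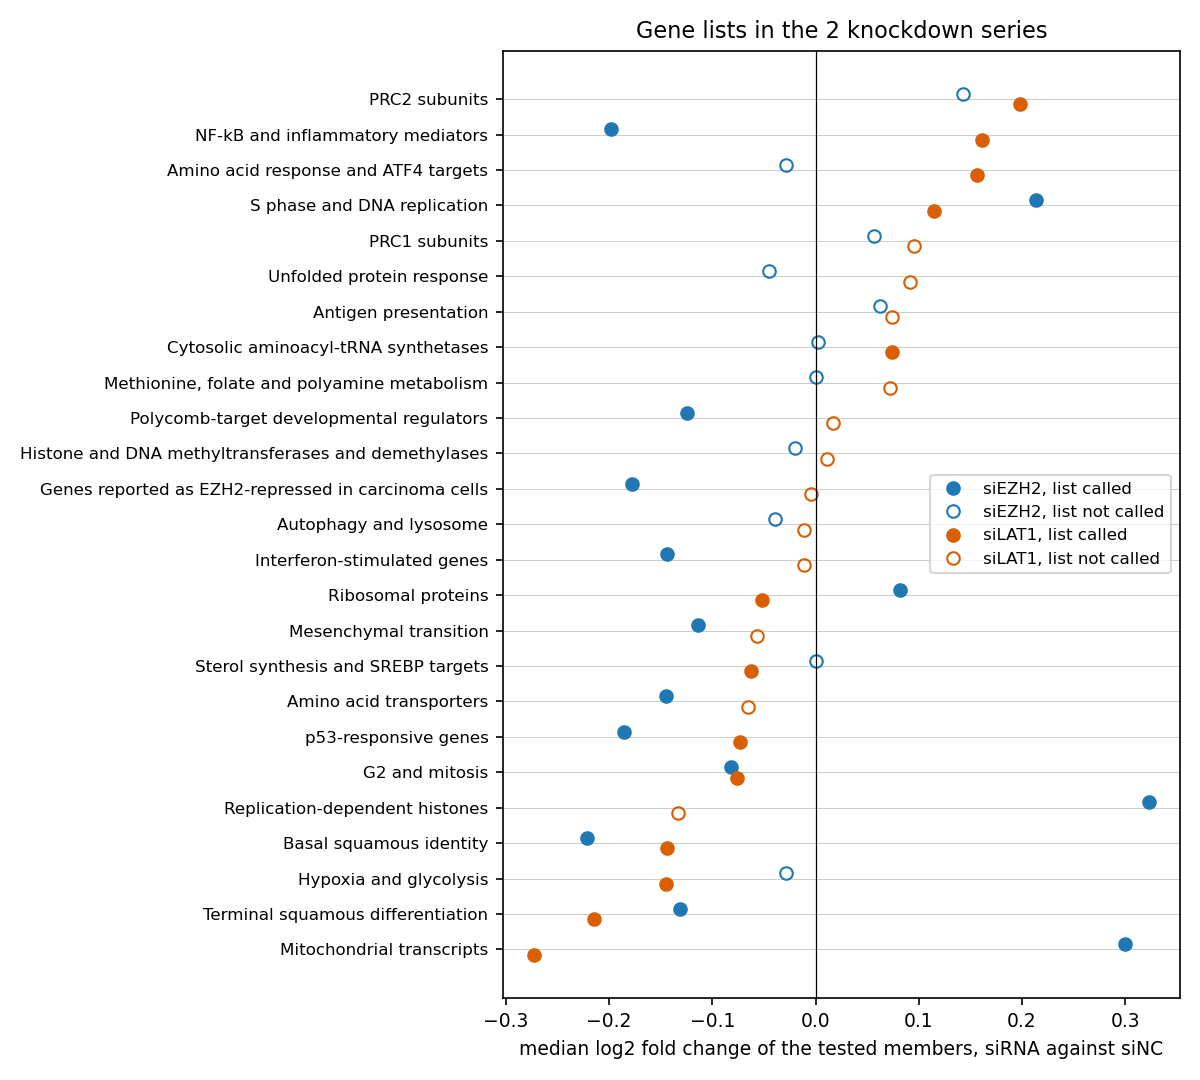
Median log2 fold change against siNC of the tested members (x axis) of each gene list (y axis) with siEZH2 (blue) and siLAT1 (orange); filled points are lists called at an adjusted p under 0.05 with a preset correlation, of which none was called with an estimated correlation. S phase genes lay above 0 with both knockdowns, and inflammatory mediators at -0.20 with siEZH2 (18 tested) and 0.16 with siLAT1 (27 tested). The members tested can differ between the series.

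The LAT1 siRNAs also differed from each other beyond their target. SLC7A5 was higher with siLAT1-3 by a log2 difference of 0.36 (adjusted p = 8.03e-04). The kinetochore gene CENPQ stood at 5.34 ± 0.099 FPKM (n = 2) with siLAT1-3 and 24.96 ± 1.46 FPKM with siLAT1-2, and the malic enzyme gene ME2 (log2 difference -1.83), the nuclear pore gene NUP43 (-1.78) and FAM210B (-1.77) were lower with siLAT1-3 too. In the other direction, CYB5R3, a cytochrome reductase gene, stood at 22.7 ± 0.665 against 4.97 ± 0.75 FPKM, and SGPL1, the sphingosine phosphate lyase gene (log2 difference 1.98), the gene ENSG00000223478 (1.62) and MIR647 (1.55) were higher with siLAT1-3. MIR647 is a short microRNA gene with few reads, and its call was lost without siLAT1-2 replicate 1 (adjusted p = 0.0567) or siLAT1-3 replicate 2 (0.0641). In all, 2981 genes differed, 1446 higher and 1535 lower with siLAT1-3. The count was 1958 without siLAT1-2 replicate 1 and 1964 without siLAT1-3 replicate 2.

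The title of the series links LAT1 to EZH2, so the calls of both knockdowns were set side by side over the 10804 genes tested in each series. Genes with large changes in both were OGFR, TPM4, NOLC1, GANAB, RGS19, ZW10, ZNF138, ZNF845 (log2 1.34 with siEZH2) and ZNF664 (log2 1.42 with siEZH2 and 1.32 with siLAT1), all of them higher. ZNF138, ZNF845 and ZNF664 belong to a family of closely related zinc finger genes, so reads shared with paralogs leave their values uncertain. SLC7A5 and TNRC6A were the only genes lower by at least 1 on the log2 scale in both, while 24 were higher by as much. EZH2 changed by -1.26 with siEZH2 and by -0.06, not called, with siLAT1. Calls in the same direction numbered 1701, with 1071 higher where chance would give 369 and 630 lower where chance would give 234. Quantile normalization gave 958 higher and 772 lower shared calls. Without siNC replicate 1 of the EZH2 series the shared calls numbered 906. Opposite calls numbered 149, where chance would give 587. Genes called with both siRNAs of each series came to 582 higher and 145 lower, where chance would give 116 and 25.7, and 15 were opposite. Across genes, which are not independent replicates, the changes of siEZH2 and siLAT1 correlated at r = 0.573 (Spearman 0.506). The 4 pairs of siRNAs from different series, which share no library, correlated at r = 0.446 to 0.464, against 0.621 for the EZH2 pair and 0.568 for the LAT1 pair, each of which shares its siNC libraries. The siNC levels of the 2 series, averaged in FPKM over libraries and then put on the log2 scale, correlated at r = 0.934 over the same genes. Single libraries of the same group had a higher r, but over the genes tested in their own series. As the tables were normalized separately, no test of a difference between siEZH2 and siLAT1 is reported.

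**Figure D3:**
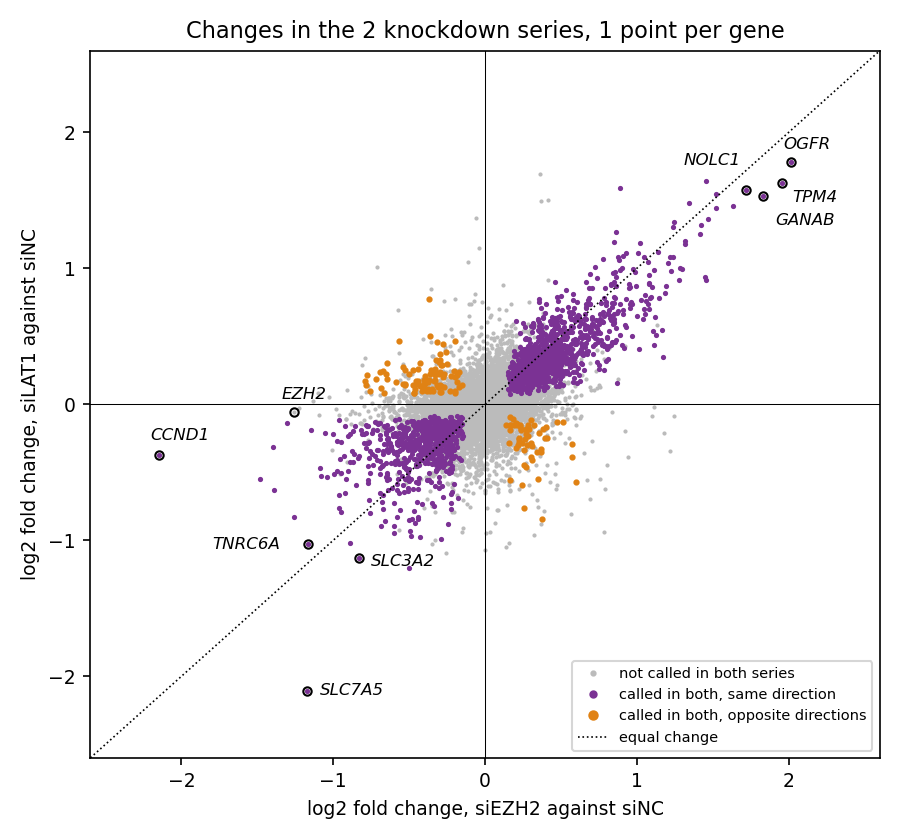
Log2 fold change against siNC with siEZH2 (x axis) and siLAT1 (y axis) of the 10804 genes tested in both series, 1 point per gene; purple points were called in the same direction and orange points in opposite directions, and the dotted line marks equal change. OGFR lies at 2.02 and 1.78, SLC7A5 at -1.17 and -2.11, CCND1 at -2.15 on the x axis, and EZH2 at -1.26 and -0.06.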

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

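The results given here are differences between the siRNAs of 1 target, each tested as the difference itself in the limma fit, and of the tests below the bound on EZH2 and the comparison of covariances were chosen after their results were seen. Between the EZH2 siRNAs 1883 genes differed, 16.3% of the 11585 tested, and 40 of the 81 gene results named in that series were among them. The named results include the 4 largest differences per direction and other genes picked for their changes. Their share therefore cannot be set against that over all genes. Log2 differences, siEZH2-2 minus siEZH2-1, were positive for 19 of the 40: RAB12 1.89, C12orf23 1.74, LEO1 1.70, MAT2B 1.70, SLC7A5 1.65, CCND1 1.49, SLC3A2 1.33, ZNF664 1.24, SUZ12 1.23, SEC23A 1.22, SCD 1.04, SLC43A2 0.625, KRT15 0.52, BMI1 0.52, SOX7 0.50, ZNF138 0.42, WBP4 0.34, TFAP2A 0.28 and IFIT3 0.24. They were negative for 21: TGFBR2 -2.025, LEPROT -1.86, MRPL24 -1.82, TMED10 -1.60, PERP -1.17, SLC7A11 -1.10, THBS1 -1.04, ANLN -0.895, HIST1H2AC -0.81, EMP1 -0.78, HIST1H2BD -0.606, UGCG -0.57, AMMECR1 -0.54, ELK3 -0.47, CDKN1A -0.435, CYR61 -0.42, DKK1 -0.365, MTRR -0.34, GATA3 -0.32, FAS -0.31 and KRT80 -0.30. As lists, the amino acid response (median log2 difference -0.167, adjusted p = 0.0461), the aminoacyl-tRNA synthetases (-0.0726, adjusted p = 0.0461) and the replication-dependent histones (-0.512, adjusted p = 2.61e-05) were lower with siEZH2-2, and the interferon-stimulated genes were higher (0.119, adjusted p = 0.0461). None of these 4 list differences was called with an estimated correlation (adjusted p = 0.531, 0.52, 0.52 and 0.52).

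Between the LAT1 siRNAs 2981 genes differed, 25.5% of the 11678 tested, and 52 of the 81 gene results named in that series were among them. The named results were picked in the same way as in the EZH2 series. Log2 differences, siLAT1-3 minus siLAT1-2, were positive for 28 of the 52: CYB5R3 2.00, SGPL1 1.98, ENSG00000223478 1.625, MIR647 1.55, F2RL1 1.502, MDM2 1.075, TNRC6A 0.93, TGFBI 0.89, HIST1H2BK 0.74, REEP3 0.74, LAMP1 0.66, SLPI 0.55, RBBP4 0.53, TOP2A 0.46, NOLC1 0.41, GANAB 0.41, CYR61 0.39, SLC7A5 0.36, CAV2 0.36, IFIT2 0.325, CBX6 0.31, SLC3A2 0.30, SLC1A5 0.25, COL4A1 0.23, GPT2 0.18, MCM3 0.14, SERPINB1 0.11 and ITGB4 0.11. They were negative for 24: CENPQ -2.03, ME2 -1.835, NUP43 -1.785, FAM210B -1.77, ADI1 -1.07, TPI1 -0.94, ENTPD7 -0.72, DSCC1 -0.67, HMGCS1 -0.67, SOD2 -0.66, IL8 -0.64, LRRC8B -0.63, RPL35A -0.51, KRT80 -0.46, ZNF664 -0.445, HOXA9 -0.34, HIF1A -0.315, MSX2 -0.31, SAMD9 -0.31, ITGA3 -0.26, CXCL1 -0.23, ZNF138 -0.225, CALR -0.18 and ORC1 -0.14. ENSG00000223478 and MIR647 may overlap other genes, and whether reads were counted by strand is not known, so their values are uncertain; MIR647 had adjusted p = 0.0567 without siLAT1-2 replicate 1. As lists, the amino acid response (median log2 difference 0.115, adjusted p = 2.34e-03), basal squamous identity (0.11, adjusted p = 3.18e-03), mitochondrial transcripts (0.205, adjusted p = 0.0391) and ribosomal proteins (0.0839, adjusted p = 3.43e-04) were higher with siLAT1-3. Sterol synthesis (-0.116, adjusted p = 7.14e-03), G2 and mitosis (-0.0943, adjusted p = 0.0127), antigen presentation (-0.101, adjusted p = 0.0371) and the NF-kB list (-0.157, adjusted p = 3.88e-03) were lower. None of these 8 list differences was called with an estimated correlation, where the adjusted p ran from 0.352 to 0.816.

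The difference that bears on the link between EZH2 and LAT1 is that SLC7A5, SLC3A2 and MAT2B, with the PRC2 subunit SUZ12, were far lower with siEZH2-1 than with siEZH2-2. Loss of EZH2 transcript as the whole cause is argued against by the siEZH2-2 minus siEZH2-1 difference of EZH2, -0.14 with an upper 95% bound of 0.0241, against 1.33 to 1.70 for SLC7A5, SLC3A2 and MAT2B; the bound was held to 0.332, the SLC3A2 difference divided by 4. Whether lower LAT1 moved its dependent genes stays open: the siEZH2-1 minus siEZH2-2 difference correlated with the siLAT1 change at r = 0.00467 across 10804 genes, but the covariance of the LAT1 siRNAs, 0.0379 after subtracting the 0.00429 that shared siNC libraries gave in simulation, did not exceed that between the series (0.0387 to 0.0404), a shared part that may cancel in this difference. The amino acid response and synthetase lists do not decide it. They were called higher with siLAT1, but not with an estimated correlation (adjusted p = 0.236 and 0.418). With siEZH2-1 against siNC they were not called (medians 0.00981 and 0.0292, adjusted p = 0.995 and 0.79). Their differences between the EZH2 siRNAs, where siEZH2-2 was lower (-0.0915 and -0.0662 against siNC), were lost with an estimated correlation (adjusted p = 0.531 and 0.52). An effect of the siEZH2-1 sequence on other transcripts is a candidate explanation. Of 83 genes lower by at least 1 log2 with siEZH2-1, 31 were also called lower with siEZH2-2 and 62.7% were not. On the same measure, the genes also called lower with the other siRNA were 38 of 73 for siEZH2-2 and 24 of 47 for siLAT1-2. For siLAT1-3 they were 18 of 49, about the share of siEZH2-1, so this measure does not set siEZH2-1 apart. EZH2 protein and activity were not tested, and siRNA sequences were not used here.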

How the results depend on the processing

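The list tests with quantile normalization and with each library left out were chosen only after the results were seen. Counts of called genes stayed within 1.5 times under quantile normalization, a pseudocount of 0.1 and a filter at a mean of 5 FPKM. Without the filter on low values, which adds many genes to the correction, siEZH2 against siNC gave 1820 genes, both EZH2 siRNAs 745, the difference between them 836, both LAT1 siRNAs 1238, the difference between them 1823 and the shared calls 853. With both siRNAs pooled as 1 group, whose difference then counts as noise, siEZH2 gave 1153 genes and siLAT1 1309, and SLC7A5 (-1.17, adjusted p = 0.211) and SLC3A2 (-0.83, adjusted p = 0.262) were no longer called in siEZH2. A minimum absolute log2 fold change of 1 left 89 and 51 genes. Residuals of equal replicate numbers in the EZH2 series correlated at -0.353 for siEZH2-1 with siEZH2-2 and 0.355 for siEZH2-1 with siNC. For siEZH2-2 with siNC the value was -0.339. These signs are those of a part shared by the groups, with the numbers of siEZH2-2 running the other way. The main fit does not model that part, and a block by the given numbers does not follow it. In the LAT1 series the correlations were 0.0177, 0.0334 and 0.0826, so there the numbers showed little pairing. With replicate number as a replicate block, 950 genes were called with both EZH2 siRNAs and 1021 between them, and the histone list was called lower in siLAT1 (adjusted p = 0.0413); the cause was not tested. With each library left out in turn, which leaves 1 group with a lone library assumed to vary like the others, the ranges were 1360 to 3360 for siEZH2, 619 to 1181 for both EZH2 siRNAs, 650 to 1499 between them, 2288 to 3602 for siLAT1, 1096 to 1529 for both LAT1 siRNAs, 1958 to 2536 between them and 906 to 1645 for the shared calls. Of 25 lists, 14 were called in siEZH2 and 13 in siLAT1 by camera, and 0 and 0 with an estimated correlation, where 4 and 5 had an unadjusted p under 0.05; fry called 15 and 21, but not the mitochondrial transcripts (adjusted p = 0.094 and 0.235) or, in siEZH2, the ribosomal proteins (0.387). The first siRNA alone called 9 lists in siEZH2, the second siRNA alone 8 in siLAT1, and quantile normalization 8 in siLAT1. Of 158 single gene results, 44 were no longer called under some setting, 42 of them when pooled, 6 without the filter and 1 (MT-CYB, adjusted p = 0.0545) with quantile normalization, and 5 without some library (PITX1, SUZ12, MT-ND5, MT-CYB and MIR647); 0 changed sign. The 6 were SUZ12 (adjusted p = 0.0669), PITX1 (0.119), SLC7A11 (0.0541), MT-ND5 (0.0725), MT-CYB (0.198) and MIR647 (0.0915). Those lost when pooled were, in siEZH2, TGFBR2, SEC23A, THBS1, ZNF664, SUZ12, BMI1, SOX7, GATA3, PITX1, SLC43A2, SLC7A11, MAT2B, SCD, ANLN, PERP, EMP1, CYR61 and HIST1H2AC, and in siLAT1, TNRC6A, REEP3, F2RL1, RBBP4, CBX6, MSX2, SLC1A5, ADI1, HMGCS1, DSCC1, TOP2A, KRT80, SLPI, TGFBI, SAMD9, CALR, SOD2, IL8, MDM2, TPI1, LAMP1, MT-CYB, RPL35A and HIST1H2BK. Quantile normalization moved the median log2 change of all genes from 0.0261 to 0.00213 with siEZH2 and from 0.0101 to -0.00784 with siLAT1. In simulated data, changes of 0.25 log2 were found for 20% of 50 genes at the EZH2 series' spread and 46% at the LAT1 series' spread. Changes of 1 were found for 100% and 98%. As few genes were changed in simulation, these rates need not hold in the real data. Count-based alternatives were not run, since the tables hold FPKM. A joint fit of the 12 libraries, planned only for counts, was tried once on FPKM and left out, so no value from it is given.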

Other observations

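The tests of the siNC control, of EZH2 in siLAT1, of siNC depth and of the median of the Polycomb targets were chosen only after the results were seen. Genes silent in siNC, below 0.1 FPKM, stayed low after knockdown: 1 of 46174 reached 1 FPKM with both EZH2 siRNAs, the microRNA gene MIR197 (1.18 and 2.03 FPKM, against 0 in siNC). With both LAT1 siRNAs 2 of 45207 did, a Y_RNA gene (1.68 and 1.79 FPKM) and a snoU13 gene (1.20 and 1.69 FPKM), both listed at 0 in siNC. These are short RNA genes with few reads, named after their values were seen.

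Genes such as OGFR, TPM4, GANAB and NOLC1 were higher with all 4 siRNAs, and all 44 genes higher by at least 1 log2 with both EZH2 siRNAs and tested in both series were called higher with both LAT1 siRNAs. A candidate explanation is a change made by the siNC control, which every comparison carries. The median ratio of the siLAT1 to the siEZH2 log2 change over the 44 genes was 0.826 (quartiles 0.711 to 0.899). Of 7 genes lower by as much, 4 were called lower with both LAT1 siRNAs, and 6 with their mean. The median ratio over the 7 was 0.433 (quartiles 0.138 to 0.556). EZH2, the target of the EZH2 siRNAs and not called with siLAT1, is 1 of the 7, so it says nothing of the siNC control. A siNC change in the 44 higher genes would not require one in the other lower genes, so the lower genes do not decide on it. Loss of EZH2 transcript after LAT1 knockdown is argued against by the lower 95% bound of the EZH2 change in siLAT1, -0.167, and siNC depth by 3 of the 4 siNC libraries lying inside the depth range of their siRNA libraries. The covariance of changes was taken over the 10804 genes tested in both series. It was 0.0387 to 0.0404 for the 4 pairs of siRNAs from different series, which share no library. For the LAT1 siRNAs it was 0.0422 and for the EZH2 siRNAs 0.0622. Of these, the chance spread of shared siNC libraries gave 0.00429 and 0.00503 in simulation. A response to any active siRNA, or shared biology of EZH2 and LAT1, stays open, since the 12 libraries include no untransfected cells and no other control siRNA.

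Developmental regulators known as Polycomb targets did not rise as a list 48 h after EZH2 knockdown. Whether EZH2 knockdown raises them in that time was left open by the median log2 change of the 18 tested, -0.125: these are targets already expressed above the filter, and their call as lower was lost with an estimated correlation (adjusted p = 0.267), without siNC replicate 2 (0.0859) and with siEZH2-2 alone (0.122). That the filter hid rises of at least 0.5 FPKM is argued against by the 73 listed genes below it, of which 0 rose that much with both EZH2 siRNAs. Smaller rises, which can be large relative to a nearly silent gene, are not covered. By any amount, 9 were higher and 5 lower with both, and 39 were at 0 in every library. EZH2 protein and the histone mark were not measured in these libraries, so remaining enzyme, a mark that outlasts it or other silencing stays open, untested.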
